A study of Homo sapiens with 6 samples.

How the data were processed

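RNA was measured in 6 libraries of LNCaP cells with a doxycycline-inducible PRMT5 hairpin, 3 from cultures given doxycycline (knockdown) and 3 from cultures without it. RNA was extracted with Trizol and libraries were made with NEBNext Ultra II reagents, per the labels' protocols. Per the submitters' processing notes, bcl2fastq, STAR 2.5, featureCounts of Subread 1.6.5 and edgeR 3.20.8 were used with genome build hg38. The series table gives, per the file headers, raw read counts per gene, which the authors deposited without normalization, and log2 CPM that the authors deposited for each library. It also holds the authors' deposited log2 fold changes and p-values with false discovery rates for doxycycline against none. The annotation, the strand setting of the counting and the filter on low counts are not given in the sources used here, so reads of genes that overlap on opposite strands may be mixed.

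The table holds 12768 genes, each above 1 CPM in 3 or more libraries, and 12547 of them in all 6. It holds 0 genes of the mitochondrial chromosome. Its coordinates overlap the GENCODE 29 (GRCh38) position of the same gene name for 1909 of 12011 genes with a single match (15.9%), although 12009 are on the same chromosome, so the coordinates are of a build other than the noted hg38, and which build the reads were aligned to is uncertain. Positions in the text come from GENCODE 29. Symbols were matched to GENCODE 29 by name for 12036 genes and through RefSeq synonyms for 410, and 322 had no match.

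The counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10 and total of 15, which removed 0 genes, robust quasi-likelihood fit, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Group means and SDs are of TMM-scaled CPM over 3 libraries, and standard errors are the log2 fold change without a prior count divided by the square root of F. Gene lists were fixed before the data were examined, 26 in all, and 25 with at least 3 measured members were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The remaining list, of mitochondrially encoded genes, had no measured member. An estimated correlation and fry were alternatives. Some genes stand on more than 1 list, such as SESN2 and GDF15 on those of p53 and ATF4.

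The text names PRMT5, WDR77, CLNS1A and KLK3 always, then the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with an average log2 CPM of at least 2 and groups that do not overlap, and in each list the 2 members with the smallest p. This rule, the designs and the alternatives listed in this section were set before the data were examined. Further fits in the later sections were not part of that plan. Other genes named were chosen after their values were seen, and a few genes that the rule takes are not reported here.

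The groups share replicate numbers, and deviations from the group means correlated between same-numbered libraries by 0.34, 0.45 and 0.17 across genes for numbers 1, 2 and 3, each above the 0.1 set for treating the numbers as pairs. However, no-knockdown replicate 3 correlated by 0.23 with knockdown replicate 1, and knockdown replicate 3 by 0.20 with no-knockdown replicate 1. Both values are above the 0.17 of number 3, so the correlations set replicate 2 apart but do not separate numbers 1 and 3 as pairs. The fit with the replicate number as a block is given as an alternative wherever it changes a call or moves a count by over 1.5 times. Counts of no pair of replicates came within sampling noise of each other (chi-square per degree of freedom 1.73 for no-knockdown replicates 1 and 3, and from 7.01 to 20.4 for the other pairs). This speaks only against a library sequenced again and cannot show that the cultures were independent. Each library was counted as 1 replicate because the series describes the cultures as biological replicates.

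Library totals of 7911853 to 15831938 reads make 3 counts worth 0.19 to 0.38 CPM. On counts simulated for the 12768 genes of this comparison with 100 genes changed 1.5-fold and 100 changed 2-fold, the fit without the block recovered 42% and 74% and called 0 unchanged genes. The blocked fit recovered 78% and 94% and called 10 unchanged genes. The counts were drawn with the replicate effects and dispersions of the blocked fit. The simulation therefore takes the numbers as true pairs and cannot show that the block suits these data. Camera and the heptamer regression were also tested on simulated data.

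The 3′ UTRs of 11483 genes (GENCODE 29, at least 50 bases) were searched for 16206 heptamers present in at least 50 genes, and blocked log2 fold changes were regressed on the presence of each, with UTR length and GC content and their squares as covariates. The search was planned after the files were seen and before its result. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size without TMM, no filter and a stricter filter, a threshold of 0.01, the block, and each library left out in turn. Scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.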

Results

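Gene expression was measured by RNA sequencing in LNCaP cells, an androgen-responsive human prostate cancer line, that carried a doxycycline-inducible short hairpin RNA against PRMT5, the main enzyme that places symmetric dimethylarginine on proteins. Doxycycline was added for 4 days in 3 knockdown cultures, and 3 cultures without knockdown grew for 4 days without it. The series describes the 3 cultures of each group as biological replicates, and it asked which genes differ after PRMT5 knockdown. The libraries held 10826534, 9870850 and 7911853 counted reads without knockdown and 10554094, 10559371 and 15831938 after it, over 12768 genes. The labels list no doxycycline-treated culture without the PRMT5 hairpin, so each difference below is that of knockdown and doxycycline together.

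PRMT5 fell from 87.8 ± 4.64 CPM (TMM-scaled read counts, SD, n = 3) to 10.4 ± 0.60 CPM (n = 3), which left 11.8% of its level. The gene lies on chromosome 14 from 22920511 to 22929585, minus strand (GRCh38, GENCODE 29). PRMT5 stood at 88.7, 91.96 and 82.8 CPM in the cultures without knockdown and at 9.69, 10.8 and 10.6 CPM in those with it, so each library sat on the side its label gives. The log2 fold change was -3.08 (SE 0.094, edgeR adjusted p = 1.37e-07). An exact two-sided permutation test of the 6 CPM values gave p = 0.1, the smallest value that 3 against 3 libraries allow. PRMT5 took 0.00097% of the reads of knockdown replicate 1 (exact binomial 95% interval 0.00079 to 0.00117%), an interval that covers counting error only.

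The mRNA of WDR77, the obligate partner of PRMT5 in the methylosome, fell from 77.8 ± 3.05 to 50.2 ± 1.41 CPM (log2 fold change -0.63, SE 0.075, adjusted p = 0.0038). CLNS1A, the partner that brings Sm proteins to the complex, had a log2 fold change of -0.14 (SE 0.093, adjusted p = 0.53). Of the 5 genes on the list of the PRMT5 complex and its partners, 2 were lower over all genes tested, 3 with the block and 3 when adjusted over the list alone. The list as a whole fell (camera adjusted p = 7.85e-05). It also did with PRMT5 itself left out of it, a test that was not planned (camera adjusted p = 0.018). The set test lost its call with an estimated correlation between genes (adjusted p = 0.22). WDR77 carries the sequence TTCCCTAA, whose first 7 bases also occur in PRMT5, in its 3′ untranslated region (UTR). Among 7 other arginine methyltransferases none passed over all genes and 1 was higher when adjusted over the list alone (camera adjusted p = 0.81). PRMT9 had a log2 fold change of 0.37 (adjusted p = 0.063, and 0.0046 with the replicate number as a block) and PRMT3 one of -0.24 (adjusted p = 0.41).

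**Figure D1:**
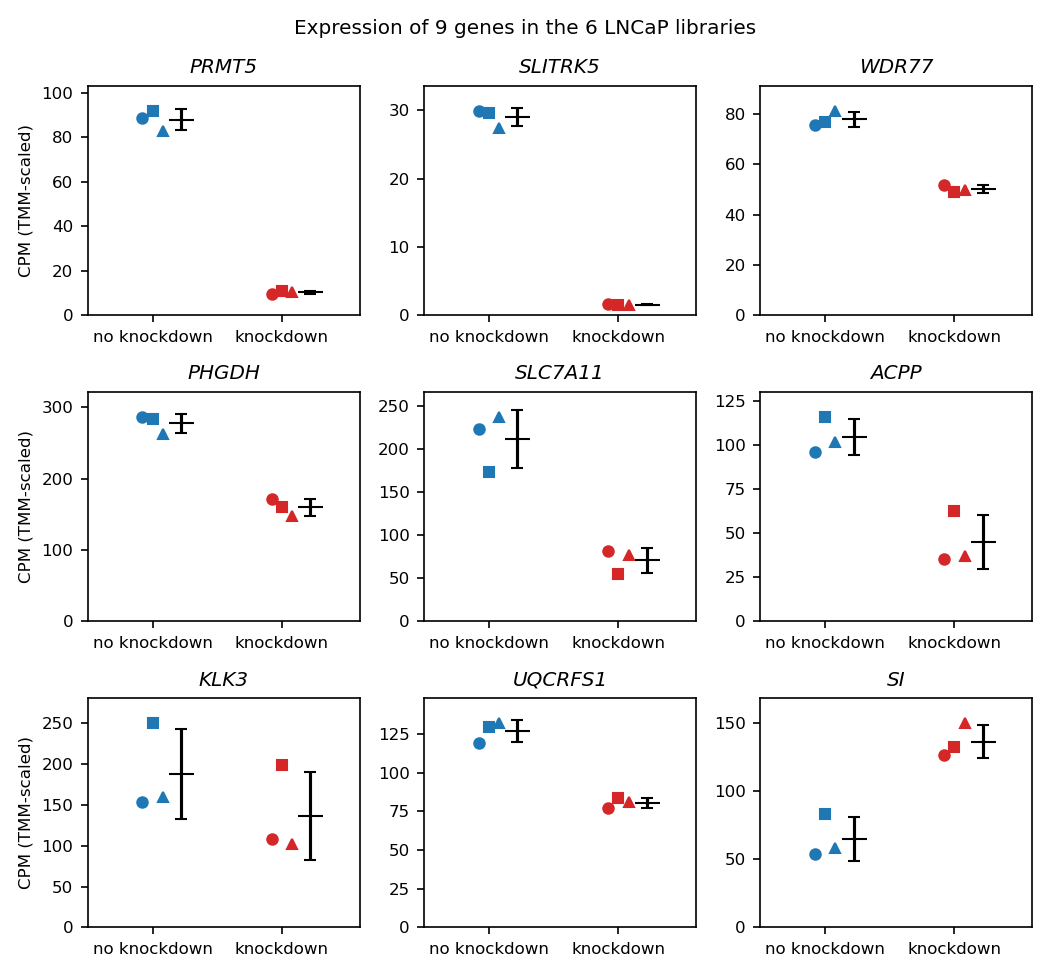
CPM (TMM-scaled, y axis from 0) of 9 genes in the 3 libraries without knockdown (blue) and the 3 with it (red); circles, squares and triangles are replicates 1, 2 and 3, and the black bar and whiskers give the mean and SD. PRMT5 drops from 87.8 to 10.4 CPM on average, while the KLK3 values of the groups overlap and are highest in replicate 2 of both groups.

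After PRMT5 knockdown more genes were called lower than higher, by a margin that differed between fits. The gene with the largest fall among those named by the fixed rule was SLITRK5, a neuronal transmembrane protein gene on chromosome 13 (87672615 to 87696272, GRCh38), which went from 29.02 ± 1.35 to 1.59 ± 0.12 CPM (log2 fold change -4.19, SE 0.14, adjusted p = 2.25e-07). TMPRSS11E, a transmembrane serine protease gene, fell by 2.32 on the log2 scale, and GALNT14, a glycosyltransferase that starts mucin-type O-glycans, fell by 2.05. BOLA3, needed to place iron-sulfur clusters in mitochondrial enzymes, fell by 1.85, and the transporter gene SLC18B1 went from 79.0 ± 1.81 to 25.7 ± 0.11 CPM. On the other side, ADAMTS6, a secreted metalloprotease gene, rose from 2.41 ± 0.37 to 6.92 ± 2.11 CPM and the adhesion receptor gene ADGRA2 from 2.29 ± 0.64 to 6.58 ± 0.93 CPM. SI, which encodes the intestinal sucrase-isomaltase, rose from 65.0 ± 15.9 to 137 ± 12.5 CPM. ZBED6CL rose by 0.97, the matrix protein gene MATN2 by 0.87 and the teneurin gene TENM2 by 0.80 on the log2 scale. The rule that chose these 12 genes requires a call and groups that do not overlap, so each changed the same way in all 3 numbered pairs by selection. Their edgeR adjusted p lay between 1.37e-07 (PRMT5) and 0.031 (ZBED6CL).

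By edgeR's quasi-likelihood test, 189 of 12768 genes passed an adjusted p of 0.05, 43 higher and 146 lower (77.2% lower), and 29 of them changed at least 2-fold, 5 higher and 24 lower. Replicate 2 of both groups deviated together from the other replicates. With the replicate number as a block 1061 genes passed, 410 higher and 651 lower (61.4% lower), of which 71 changed at least 2-fold, 25 higher and 46 lower. All 189 genes passed in the blocked fit in the same direction. The share of lower genes among those called ran from 53.1% (1122 higher, 1269 lower, with the block and without pair 2, a fit chosen after seeing the data) to 90% (without knockdown replicate 3). The authors' deposited table lists 472 genes under a false discovery rate of 0.05, 130 higher and 342 lower, among them all 189. The groups did not overlap for 19.8% of genes, where chance gives 10%. The median standard error of a log2 fold change was 0.11, and 0.091 with the block. The median log2 fold change of all genes was 0.00 (-0.0021). Without no-knockdown replicate 1, no-knockdown replicate 3, knockdown replicate 1 or knockdown replicate 3 the count of genes past the threshold was 52, 29, 24 or 30, and without knockdown replicate 2 it was 445. Among the named genes, SLITRK5, TMPRSS11E, GALNT14, BOLA3, SLC18B1, MATN2, WDR77, PHGDH, SLC7A11 and UQCRFS1 kept their calls in each of these fits and each other alternative fit, and the other 15 called genes that the fixed rule names lost theirs without at least 1 of the libraries.

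**Figure D2:**
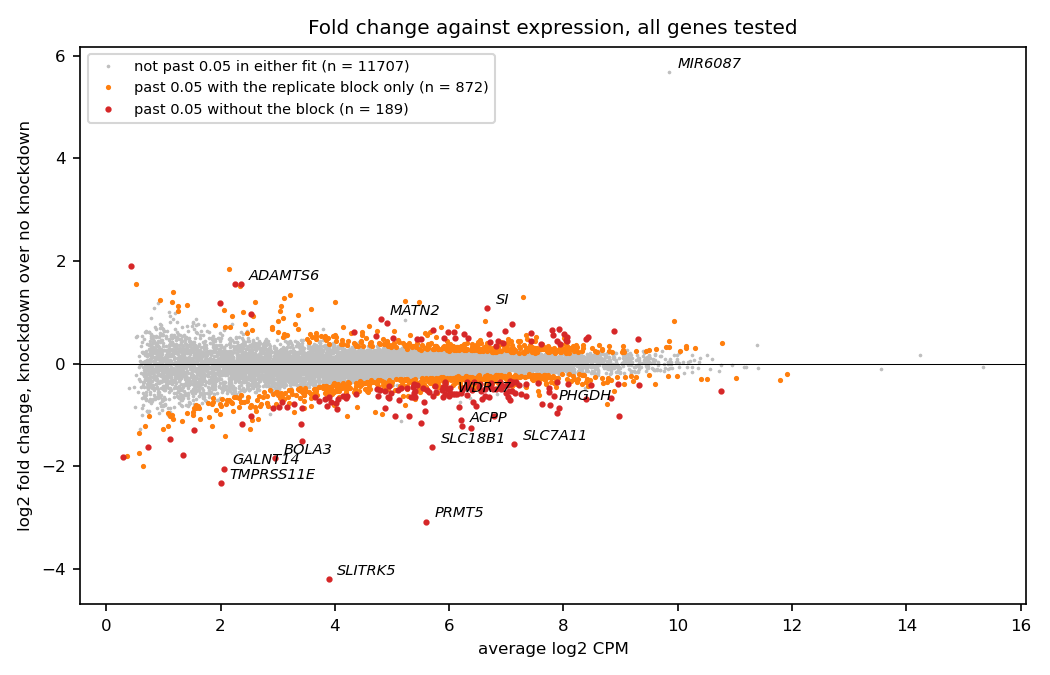
Log2 fold change (knockdown over no knockdown, y axis) against average log2 CPM (x axis) of the 12768 genes. Red points passed an adjusted p of 0.05 in the fit without the replicate block (189 genes), orange points only with it, and grey points in neither. MIR6087, at the top, rests on 1 library.

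Genes that carry a particular 7-base sequence in their 3′ UTR were lower after knockdown than genes without it. This sequence was picked because, of 16206 heptamers searched, it had the strongest association with lower blocked fold changes. The sequence, TTCCCTA, occurs once in the PRMT5 mRNA, in coding exon 15 of transcript PRMT5-201 (chromosome 14, 22922181 to 22922187, GRCh38). In the blocked fit the median log2 fold change was -0.08 (bootstrap 95% interval -0.10 to -0.05) for 481 genes with TTCCCTAA, -0.03 (-0.05 to -0.02) for 948 genes with TTCCCTA not followed by A, -0.01 (-0.03 to 0.01) for 614 genes with only TCCCTAA, -0.0016 (-0.02 to 0.01) for 679 genes with TTCCCTA only outside the 3′ UTR, and 0.01 (0.00 to 0.01) for 8761 genes with none of these. In the same order, 16.0%, 8.97%, 8.31%, 6.04% and 4.09% of the genes were called lower, and 3.12%, 3.69%, 3.58%, 3.53% and 3.33% higher. These medians and shares are not matched for UTR length. The intervals resample genes as if they were independent and leave out the spread between cultures, so they may be too narrow. Of 612 searched genes lower with the block, 162 carry TTCCCTA in the 3′ UTR, where 92.4 were expected from genes of like UTR length. This excess comes from the same fold changes that picked the sequence, so it is not a separate test. RNF14, a RING-type ubiquitin ligase gene (log2 fold change -1.25), TMEM170A (-1.11), the proteoglycan gene SDC1 (-1.01) and BOLA3 carry TTCCCTAA in the 3′ UTR, and the lipase gene ABHD2 (-1.03) and SLC7A11 carry TTCCCTA. The genes RNF14, TMEM170A, SDC1 and ABHD2 fall outside the fixed rule and were chosen after their values were seen. SLITRK5 holds only TCCCTAA there, TMPRSS11E and GALNT14 hold TTCCCTA elsewhere in the mRNA, and no site was found in SLC18B1.

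**Figure D3:**
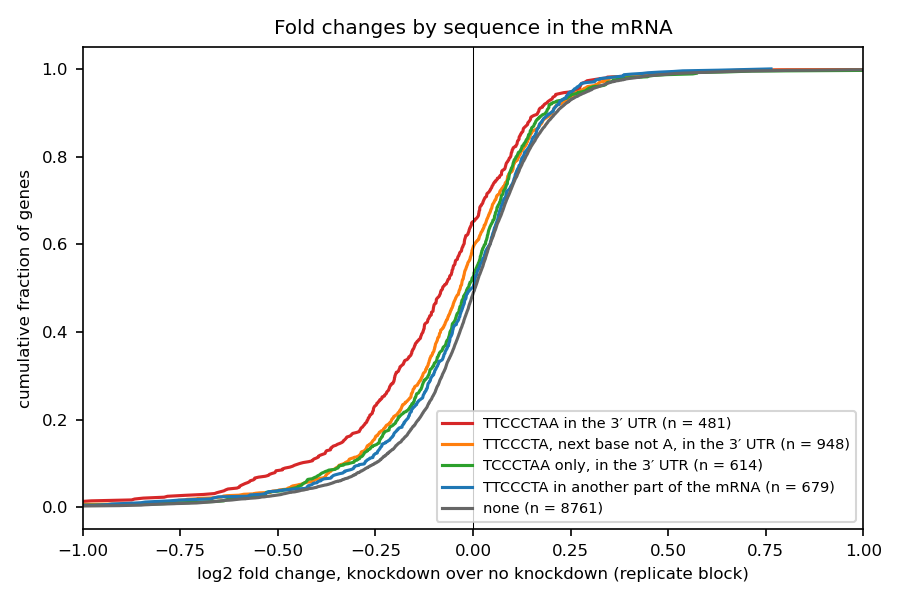
Cumulative fraction of genes (y axis) against log2 fold change (knockdown over no knockdown, replicate block, x axis, drawn from -1 to 1) for genes grouped by the sequence their mRNA holds. The curve of the 481 genes with TTCCCTAA in the 3′ UTR lies furthest to the left, with a median of -0.08, and that of the 8761 genes without a site has a median of 0.01.

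Genes of the integrated stress response and amino acid supply fell together. Their list, fixed around the transcription factor ATF4, had 32 measured members with a median log2 fold change of -0.36, and 32 of the 32 lay below 0. Of these, 8 were lower and none higher over all genes, 21 were lower when adjusted over the list alone, and 19 were lower with the replicate block (27 adjusted over the list alone). SLC7A11, the cystine importer on chromosome 4, fell from 212 ± 33.7 to 70.9 ± 14.4 CPM (log2 fold change -1.57, SE 0.17, adjusted p = 0.0045). PHGDH, which starts serine synthesis, fell from 277 ± 13.5 to 160 ± 11.8 CPM (log2 fold change -0.80, SE 0.078, adjusted p = 0.0011), and PSAT1, the next enzyme, from 166 ± 12.2 to 101 ± 11.7 CPM. Asparagine synthetase (ASNS) fell by 0.60, the mitochondrial folate enzyme gene MTHFD2 by 0.64, NUPR1 by 0.54, ATF4 itself by 0.47 and CEBPG by 0.41 on the log2 scale. The list fell by camera (adjusted p = 5.32e-15) and by fry (adjusted p = 0.042). The fry call was lost with the replicate block (adjusted p = 0.072), and the camera call with an estimated correlation (adjusted p = 0.48). TTCCCTA or TCCCTAA lies in the 3′ UTR of 5 of the 32 members, and 18 of the 19 members lower with the block, all but SLC7A11, lack both.

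Androgen-induced genes shifted down by small steps. Of 38 measured, 31 lay below 0 with a median log2 fold change of -0.14, but only SORD, a sorbitol dehydrogenase gene, passed over all genes (133 ± 5.82 to 104 ± 3.59 CPM, log2 fold change -0.36, adjusted p = 0.037), and when adjusted over the list alone 3 were lower and 1 higher. With the replicate block 11 were lower and 2 higher. KLK3, which encodes prostate-specific antigen, had 188 ± 54.6 and 137 ± 53.9 CPM (log2 fold change -0.46, SE 0.31, adjusted p = 0.58), and the blocked fit gave an adjusted p of 4.56e-04, with KLK3 lower in 3 of 3 pairs. TMPRSS2, a serine protease gene, had an adjusted p of 0.48 and of 0.0017 with the block. UAP1 had a log2 fold change of 0.36 (adjusted p = 0.095, 0.0020 with the block). The list fell by camera (adjusted p = 0.0043), and not with an estimated correlation (adjusted p = 0.22). KLK3 was higher in replicate 2 of both groups than in replicates 1 and 3, by 0.80 on the log2 scale.

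Of 9 androgen-repressed genes measured, 3 fell and none rose over all genes. These were UGT2B15 (561 ± 16.7 to 350 ± 45.2 CPM, adjusted p = 0.010) and UGT2B17 (log2 fold change -0.54, adjusted p = 0.021), which glucuronidate androgens, and the opioid receptor gene OPRK1 (312 ± 8.30 to 171 ± 40.8 CPM, adjusted p = 0.021). The 2 UGT2B genes are close copies, so the split of reads between them is uncertain. With the replicate block 4 were lower and 2 higher, DDC (log2 fold change in that fit -0.81, adjusted p = 2.25e-05) joining these 3, and ACKR3 (0.46, adjusted p = 6.69e-04) and NOV (0.56, adjusted p = 0.018) being the higher ones. Adjusted over the list alone, 4 were lower and 3 higher. The list did not pass by camera (adjusted p = 0.23), and it passed downward by fry (adjusted p = 0.042, 0.072 with the block). Of 14 luminal prostate markers, ACPP, which encodes prostatic acid phosphatase, fell from 105 ± 10.3 to 45.1 ± 15.3 CPM (log2 fold change -1.22, adjusted p = 0.032) and was the only one past the threshold, both over all genes and adjusted over the list alone, and 3 were lower with the block. KRT18 had a log2 fold change of -0.24 (adjusted p = 0.23, 0.027 with the block), and the list had a camera adjusted p of 0.97. Among 4 basal markers (DST -0.29, ITGB4 -0.07) and 4 neuroendocrine markers (ENO2 -0.09, SYP -0.26) none passed over all genes or adjusted over the list alone (camera adjusted p = 0.81 for each), and DST alone passed with the block (adjusted p = 0.033).

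Targets of p53 shifted upward as a list, although its only called member fell. Of 34 measured, 26 lay above 0 with a median log2 fold change of 0.15 (camera adjusted p = 4.64e-04, and 0.48 with an estimated correlation), and fry did not pass (adjusted p = 0.26, 0.072 with the block). SESN1, a sestrin that restrains mTORC1 signalling, fell from 257 ± 14.8 to 175 ± 22.5 CPM (adjusted p = 0.020). Adjusted over the list alone, 2 were higher and 1 lower, and with the block 8 were higher and 1 lower, the higher ones including ZMAT3 (132 ± 20.7 and 193 ± 42.3 CPM, adjusted p = 1.20e-04 with the block), BAX (0.039), CDKN1A (0.013) and DDB2 (0.019). DDB2, a sensor of damaged DNA, had 25.1 ± 0.41 and 32.6 ± 1.13 CPM (adjusted p = 0.069 without the block).

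Genes of DNA break repair showed no called member without the block. None of 33 homologous recombination and break signalling genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.60), with H2AFX at a log2 fold change of 0.35 (adjusted p = 0.18, 0.047 with the block) and BRCA1 at -0.39 (adjusted p = 0.21). With the block 2 were higher, H2AFX and RAD50 (log2 fold change in that fit 0.35, adjusted p = 0.0056). None of 13 end joining genes passed either (camera adjusted p = 0.81; DCLRE1C -0.32, NHEJ1 -0.32). None of 43 DNA replication and G1/S genes passed (camera adjusted p = 0.81), with the helicase subunit gene MCM6 at -0.49 (adjusted p = 0.13, 0.0061 with the block) and RRM2 at 0.61 (adjusted p = 0.21). With the block 2 of them were lower, MCM6 and CHAF1B (-0.49 in that fit, adjusted p = 0.025), and 1 was higher, MCM7 (0.30, adjusted p = 0.035). Mitotic genes had a median log2 fold change of 0.15 and 27 of 36 above 0, with none called over all genes or adjusted over the list alone (ANLN 0.41, ASPM 0.49). Their camera adjusted p was 0.038, 0.072 with the block and 0.93 with an estimated correlation, and fry gave 0.82 (0.76 with the block). Without no-knockdown replicate 1, no-knockdown replicate 3 or knockdown replicate 3 the camera adjusted p was 0.21, 0.35 or 0.67. The lowest adjusted p of the mitotic list over the alternatives run, by camera or fry, was 2.62e-05. Of 16 replication-dependent histone genes, the linker histone gene HIST1H1C fell from 566 ± 29.5 to 428 ± 21.4 CPM (adjusted p = 0.031), HIST1H2BG had a log2 fold change of 0.38 (adjusted p = 0.095, 0.018 with the block), and the list did not pass (camera adjusted p = 0.36). Adjusted over the list alone, 1 histone gene was higher and 1 lower.

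Sm proteins, which PRMT5 methylates, and their assembly factors showed no called mRNA among 24 measured (camera adjusted p = 0.81; LSM11 -0.30, SNRPB2 0.17). Among 32 splicing regulators none passed over all genes or adjusted over the list alone, with a median log2 fold change of 0.07 and 22 above 0 (camera adjusted p = 0.060; SRSF11 0.17, U2AF2 0.17). Without no-knockdown replicate 2 both lists passed upward by camera, at adjusted p of 0.020 for the Sm list and 0.0019 for splicing regulators. Over the alternatives run, the adjusted p of splicing regulators by camera or fry went from 0.0014 to 0.71. Exon usage was not analysed here, since the table holds 1 count per gene.

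Cholesterol and fatty acid synthesis genes lay mostly higher. Of 32 measured, 25 were above 0 with a median log2 fold change of 0.16 (camera adjusted p = 0.0012, and 0.55 with an estimated correlation), and fry did not pass (adjusted p = 0.26, 0.064 with the block). Over all genes, and also adjusted over the list alone, 1 was higher and none lower. With the block 9 were higher, among them INSIG1 (135 ± 3.79 and 167 ± 17.2 CPM, adjusted p = 0.0089) and SQLE (0.0034), and 1 was lower. Of 19 endoplasmic reticulum chaperone and stress genes, the co-chaperone gene DNAJB9 rose from 53.4 ± 1.13 to 81.6 ± 9.44 CPM (adjusted p = 0.014) and XBP1, a transcription factor of the unfolded protein response that carries TTCCCTAA in its 3′ UTR, fell from 186 ± 8.24 to 141 ± 8.35 CPM (adjusted p = 0.029). Adjusted over the list alone, 1 was higher and 4 lower (camera adjusted p = 0.23). With the block 1 was higher and 4 lower over all genes, EDEM1 (adjusted p = 0.014), HERPUD1 (0.020) and SEL1L (0.0029) joining XBP1. The list passed downward by fry (adjusted p = 0.042), and not with the block (0.072).

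Nuclear genes of oxidative phosphorylation moved little. Of 43 measured, UQCRFS1, the Rieske iron-sulfur subunit of complex III, fell from 127 ± 6.99 to 80.5 ± 3.34 CPM (log2 fold change -0.66, SE 0.075, adjusted p = 0.0031) and was the only one called, over all genes and adjusted over the list alone, with NDUFB8 at -0.25 (adjusted p = 0.20). The list did not pass (camera adjusted p = 0.81), nor did 39 mitochondrial ribosome genes (camera adjusted p = 0.97; MRPS2 0.24, MRPL45 0.24), 25 genes of glycolysis and the hypoxia response (0.38; HK2 -0.45, PFKP -0.49) and 32 genes of MYC and ribosome biogenesis (0.81; GNL3 -0.26, RRP12 -0.22). In these 3 lists none passed over all genes or adjusted over the list alone, while with the block MRPS14 (adjusted p = 0.049), HK2 (0.026), PFKP (0.0071), PFKM (0.010) and GNL3 (0.012) were lower and EGLN3 (0.013) was higher. The glycolysis list had a fry adjusted p of 0.10, and passed downward with the block (0.041). Genes on the mitochondrial chromosome were not analysed here.

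Interferon-stimulated genes lay more often below 0 than above it, by a shift whose call depended on the alternative. TRIM25, a ubiquitin ligase of RIG-I signalling, was the only member called over all genes (133 ± 11.1 to 94.5 ± 4.95 CPM, log2 fold change -0.49, adjusted p = 0.020). Of 28 measured, 19 lay below 0, 4 were lower when adjusted over the list alone and 6 were lower with the block, among them IFIT2 (17.6 ± 2.18 and 11.4 ± 0.89 CPM, adjusted p = 0.054, 0.0037 with the block). The list had a camera adjusted p of 0.038, of 0.070 with the block and of 0.71 with an estimated correlation, and fry gave 0.38 (0.11 with the block). When genes with TTCCCTA or TCCCTAA in the 3′ UTR were left out, the camera adjusted p was 0.054 (0.099 with the block). Without no-knockdown replicate 1, no-knockdown replicate 3 or knockdown replicate 2 it was 0.21, 0.23 or 0.31. Over the alternatives run, the list's adjusted p by camera or fry went from 0.0010 to 0.71, so some kept the call. Of the markers of cells that a culture of this line should not hold, 9 fibroblast and mesenchymal genes were measured, with none called over all genes, 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.81; VIM -0.65 with an adjusted p of 0.065, COL3A1 0.59 with 0.083, and 0.0071 and 0.011 with the block). None of 4 leukocyte and endothelial markers passed over all genes or adjusted over the list alone (camera adjusted p = 0.81; HLA-DRA 0.50, VWF -0.26).

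**Figure D4:**
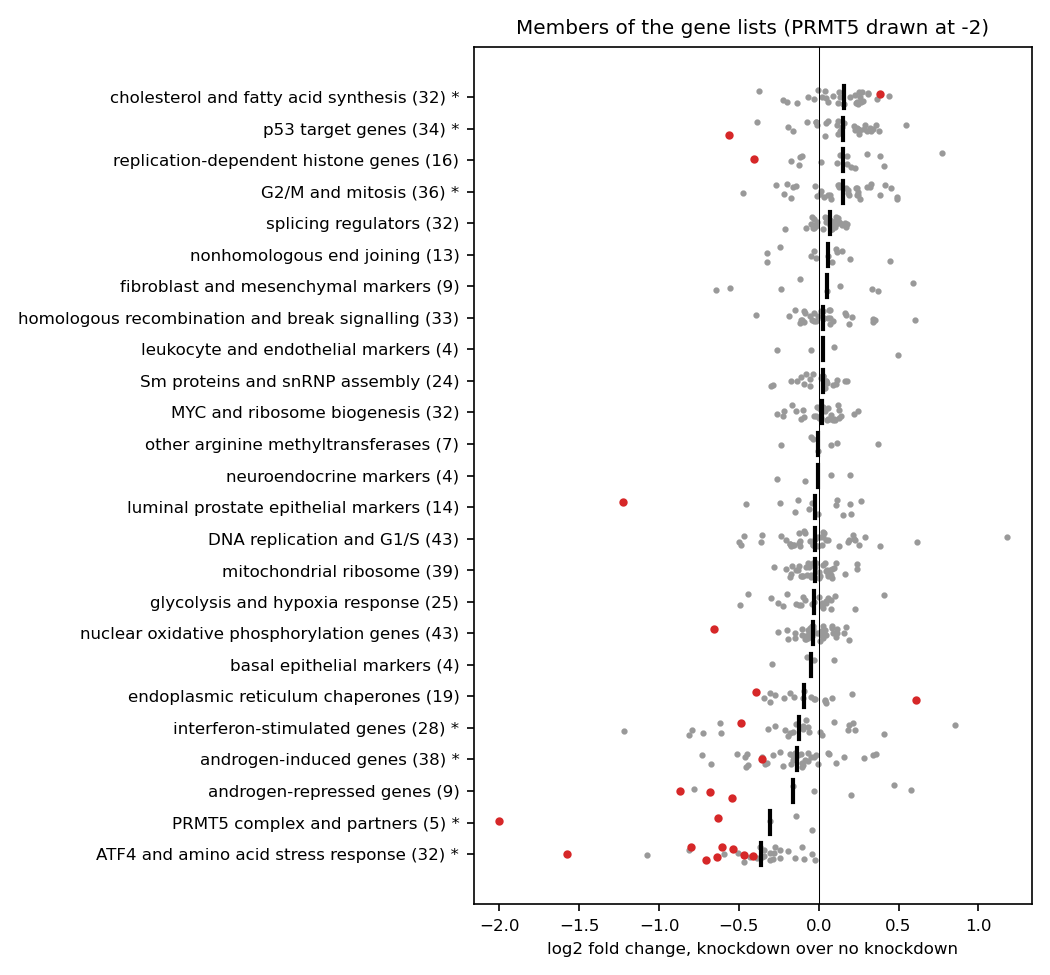
Log2 fold change (knockdown over no knockdown, x axis) of each measured member of the 25 gene lists, with the number of members in brackets. Red points passed an adjusted p of 0.05 over all genes, black bars are list medians, stars mark lists with a camera adjusted p under 0.05, vertical scatter within a list has no meaning, and PRMT5 is drawn at -2 instead of -3.08. All 32 points of the ATF4 list lie below 0.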

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

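PRMT5 was lower under every alternative run, and no gene called without the block changed direction in any of them. The filters removed 0 genes, so they test nothing. With the replicate block 1061 genes passed (410 higher, 651 lower, 71 at least 2-fold). DESeq2 called 303 (91 higher). At a threshold of 0.01 the count was 43. Leaving out 1 library gave from 24 to 445 genes (higher 3 to 179, lower 21 to 266, at least 2-fold 13 to 64), of which at least 24 were among the 189. Chosen after seeing the data, leaving out both replicate 2 libraries gave 2141 (976 higher, 1165 lower, 109 at least 2-fold). Also outside the plan, the replicate block gave 455 (177, 278 and 67) without pair 1, 2391 (1122, 1269 and 104) without pair 2 and 412 (139, 273 and 49) without pair 3. The replicate block with GC and length trends removed, likewise outside the plan, gave 1760 (806, 954 and 73). The cause of these changes was not tested, beyond the fewer libraries in fits that leave some out. Camera called 7 lists, 5 with the block and 0 with an estimated correlation. The block changed no call of the 25 called genes named besides PRMT5. At these depths 42% of simulated 1.5-fold changes were recovered without the block and 78% with it. The simulation took the replicate effects of the blocked fit as real, and depth was not varied in it. Without genes that carry a 3′ UTR site, chosen after seeing the data, camera called 6 lists, having lost the interferon list, and 5 with the block.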

Other observations

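The tests of doxycycline acting on mitochondria and of GC content or gene length trends in replicate 2, the comparison of site types, the tests of replicate 2 against replicates 1 and 3 and each fit without genes that carry a site were chosen after the result was seen. Several genes with a rise of at least 2-fold passed the threshold only with the replicate block. FRY, which encodes a microtubule-binding protein, had 90.9 ± 25.3 CPM without knockdown and 222 ± 91.0 CPM with it (SD, n = 3), and the zinc finger gene ZNF703 had 22.3 ± 8.67 and 51.6 ± 10.7 CPM. Both had an edgeR adjusted p of 1.09e-05 with the block and were higher in 3 of 3 pairs, against 0.20 and 0.11 without it. GCG, the proglucagon gene, had 26.4 ± 8.13 and 60.6 ± 29.8 CPM (adjusted p = 1.08e-04 with the block, 0.31 without). Among the falls, PSMB5, a catalytic subunit of the proteasome, went from 149 ± 14.5 to 73.2 ± 1.82 CPM (adjusted p = 4.33e-04 without the block), and the glutamine transporter gene SLC1A5 had 25.2 ± 7.11 and 12.4 ± 2.43 CPM (adjusted p = 6.24e-04 with the block, 0.064 without).

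In replicate 2 of both groups, 1652 genes differed from replicates 1 and 3 by edgeR (599 higher, 1053 lower), with KLK3 higher by 0.80, SYT4 by 1.31, and NEAT1 at -0.97 and IGFBP3 at -1.66 on the log2 scale. Of the 25 lists, the Sm list (camera adjusted p = 0.0020), nuclear oxidative phosphorylation genes (0.029) and histone genes (0.021) were higher in replicate 2, and the ATF4 list (0.0020) and interferon-stimulated genes (0.021) lower. With an estimated correlation none of these passed (adjusted p = 0.62, 0.71, 0.62, 0.73 and 0.62 in that order).

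MIR6087, a gene model of 49 bases, had 81932 reads in knockdown replicate 3 and from 91 to 1379 in the other 5 libraries.

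Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave as many as 189 genes, and the highest count of any other split by edgeR was 0. At an unadjusted p under 0.05 the real split gave 1792 genes and the highest of the others, which keeps both replicate 2 libraries in 1 group, 1730. These are too few splits for a share under 0.05. With the block, 4 splits part every numbered pair. The real one gave 1061 genes and the highest of the others 0. Every other split, with or without the block, mixes knockdown and control cultures within its groups. Real changes then add to the spread within groups, so these low counts are not a chance baseline.

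The first pattern is the fall of genes that carry TTCCCTA in the 3′ UTR. Of 16206 heptamers it had the strongest association with lower fold changes (t = -8.99 over n = 11483 genes, Bonferroni-adjusted one-sided p = 3.34e-16 over the 2283 that occur in the PRMT5 mRNA), TCCCTAA, which overlaps it in TTCCCTAA, came second (t = -7.93; median of the 614 genes with only TCCCTAA -0.01, 95% interval -0.03 to 0.01) and the largest t in the other direction was 5.90 (TTTTGTT); 6 heptamers passed a Bonferroni adjustment over all 16206 for lower and 12 for higher fold changes, so the test also passes other sequences, among those of PRMT5 ACAGAGA (adjusted over 2283, 0.0019; in 12 of the 38 genes below, 8.59 expected). TTCCCTA is in 12 of 38 searched genes at least 2-fold lower with the block, where 5.97 were expected from genes of like UTR length. It was picked on these same fold changes, so this excess is not separate support. The regression takes genes as independent and leaves out the spread between cultures, so its p may be far too small. Of the heptamers tested, 14.1% occur in the PRMT5 mRNA, so an unrelated top heptamer could occur there too. A candidate explanation is silencing of other mRNAs by the seed of a hairpin RNA against this part of PRMT5. Such silencing may extend to WDR77, SLC7A11, RNF14 and BOLA3. For the genes at least 2-fold lower, a shared loss of the region around PRMT5 is argued against by the 25 other genes within 1 Mb (median log2 fold change -0.021, 95% interval over genes -0.09 to 0.12). Of these 25, 2 were lower and 0 higher with the block, so an effect on single neighbours stays open. The hairpin sequence was not used here and the labels list no cultures with another hairpin, so for a gene with a site, loss of PRMT5 and a seed effect stay open, and 26 of the 38 genes lack the heptamer.

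The second pattern is the fall of the ATF4 list (camera adjusted p = 5.32e-15, from 4.65e-21 to 0.48 over the alternatives tried, the latter with an estimated correlation, and 0.66 with both that and the block). Doxycycline is known to block mitochondrial protein synthesis, which raises this response. The list's median log2 fold change of -0.35 with the block (95% interval -0.47 to -0.29) lies on the other side of 0. That interval resamples the 32 members as if they were independent and leaves out the spread between cultures, so it may be too narrow. GC content or gene length bias is argued against because 100% of the 19 members lower with the block stayed so once both trends were removed, and a difference in depth because 94.7% did with every library thinned to 7911853 reads. Silencing of the members through their own sites is unlikely as the whole source, since without genes carrying a site the list still fell (camera adjusted p = 1.33e-15, 4.73e-14 with the block), but a seed effect on an upstream gene was not tested and stays open: EIF2AK3, which encodes the kinase PERK upstream of ATF4 and was chosen after its value was seen, holds only TCCCTAA and had a log2 fold change of -0.59 (adjusted p = 0.0076, 1.71e-04 with the block). Loss of PRMT5 and another effect of doxycycline, given only to knockdown cultures, stay open too and were not tested, since the labels list no culture with another hairpin and none with a control hairpin and doxycycline.

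The third pattern is the distance of both replicate 2 libraries from the others. The genes and lists that differ are given above. Depth is argued against as the cause, since the deviations of the replicate 2 libraries still correlated by 0.42 across genes at equal depth. Without the 4 abundant noncoding RNAs RPPH1, MALAT1, RMRP and MIR6087 the correlation was 0.47. Leaving out 4 of 12768 genes could hardly move it, so this test decides nothing about them. Longer genes were lower in replicate 2 (Spearman's rho across genes -0.25 with length), but removing GC and length trends left a correlation of 0.50, so these trends are not the whole cause. A shared day, passage or RNA preparation may be behind it, and so may a difference in the state of the cells, since no label gives a batch and the list tests cannot tell these apart.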
